A study of Vitis vinifera with 6 samples.

How the data were processed

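Cabernet Sauvignon berries were sampled in Changli (Hebei, eastern China, 212 m) and in Gaotai (Gansu, western China, 1377 m) at E-L 31 (pea-size berries), E-L 35 (the onset of ripening, véraison) and E-L 38 (harvest). The labels give 10-year-old own-rooted vines, 300 berries per replicate and RNA from about 50 deseeded berries, and each region and stage is represented by 1 library, so the 6 libraries hold no replicate of any group. The sequencer was an Illumina HiSeq 2000.

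Per the file headers, the authors assigned reads uniquely to assembled transcripts (unigenes), and the deposited count is the number of uniquely assigned reads per unigene. The deposited RPKM is that count per kilobase of unigene and per 1000000 assigned reads; recomputing it from the counts, the lengths and the header totals gave the same values to within rounding. The assembler, the aligner and their versions are not given in the sources used here. A unigene without a read is absent from a library's table and was taken as 0 counts. Library totals lay between 8143 and 8929 in units of 1000 reads, and 47856 unigenes had a read in at least 1 library. Names are the best protein match in the deposited annotation, so they are matches by similarity and not gene models. Unigenes have no genome coordinates, and 21455 of them share their matching protein with another unigene, so single members of close families (chalcone synthases, stilbene synthases, small heat shock proteins) are uncertain.

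Counts were fitted with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test) in R 4.3.3, with stage and region as additive terms and 2 residual degrees of freedom. The error is therefore how far the region difference changes from stage to stage, and not a spread between vines. The fit tested 28799 unigenes, and adjusted p is by Benjamini-Hochberg with a threshold of 0.05. Values after ± are the absolute log2 fold change divided by the square root of F. They are not standard errors of the estimate and can lie below the counting error where a level has few reads. Fold changes between regions are Gaotai over Changli; those between stages are the later stage over the earlier. The TMM factors were 1.26 and 1.25 at E-L 31, 0.933 and 0.943 at E-L 35, and 0.914 and 0.792 at E-L 38, for Changli and Gaotai.

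Within a stage the regions were compared by the ratio of TMM-scaled CPM (reads in 1000000), with the exact 95% Clopper-Pearson interval of the conditional share turned into a ratio. These intervals and the floors below cover counting error only. No test was made there, because each side is 1 library. A unigene counted as apart when the ratio was at least 2-fold and the interval excluded 1, among the 30639 with at least 1 CPM in at least 2 libraries. Where the lower side had 0 reads the ratio is a lower bound, computed with a floor of 3 reads over the group, which lies somewhat above the lower limit of the exact interval; with 1 to 3 reads the ratio of counts is given with its interval.

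The 30 gene lists, the fits, the thresholds and the rule for naming genes were set before the data were examined. Lists were drawn by words in the descriptions, which has side effects: most members of the flavonol list and many of the flavonoid core list are reductases resembling dihydroflavonol 4-reductase (DFR), a misspelled dioxygenase (LDOX) was missed by the flavonoid core list, the ethylene list caught a sterol methylene enzyme, and the anthocyanin list holds a homeobox protein named ANTHOCYANINLESS. The lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated one, adjusted over the 30 lists. Within a stage the median log2 ratio of a list, with 0.5 reads added in proportion to library size, was placed among 10000 random lists matched on mean expression. The random lists draw unrelated unigenes and so ignore the correlation between members of a list. In the regional fit it was estimated at 0.502 for photosynthesis, 0.454 for heat shock and -0.005 for lipoxygenases. The percentiles are therefore descriptive and not tests. The added reads were first not scaled to library size; this was changed after the values had been seen, because it gave unigenes without reads a ratio other than 1.

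The rule named the 8 unigenes with the largest rise and the 8 with the largest fall among those past the threshold with the same sign in every matched pair of libraries, at least 20 CPM in the higher level and a description; where fewer passed, the list was filled with unigenes that did not pass, and these are given as such. It also named the 2 extreme members in each direction of each list and a set of flavonoid genes and regulators. Within a stage it named the 4 highest and 4 lowest ratios among unigenes with a description and at least 200 reads in the higher library. The planned locus identifiers of the flavonoid set matched nothing in the deposited tables, so 24 unigenes were matched by description before their fold changes were looked at. AOMT, MYBA2 and MYBPA1 had no match.

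Correlations across genes used log2 CPM with 2 reads added in proportion to library size, between differences that share no library, except those with the ripening step next to a stage, which share both libraries of that stage; genes are not independent replicates, so they carry no p. Alternatives were DESeq2 size factors, library size alone, no filter, a filter of 5 CPM, the DESeq2 1.42.0 Wald test, limma on the deposited RPKM with 1 or 0.1 added, an adjusted p of 0.1, designs without the block, and leaving out each library in turn. Data were simulated with the trended dispersion of the fit and with changes in well-read unigenes alone. Dispersion particular to single unigenes was left out. On these data the regional fit recovered 14.9% of changes of 1 on the log2 scale, 91.0% of changes of 2 and 100% of changes of 4, with 2 false calls. The fits between stages recovered 65.7% and 64.2% of changes of 2, for E-L 35 over 31 and E-L 38 over 35. Simulated single libraries without a difference were counted as apart for 1.13%, 1.28% and 1.37% of unigenes at E-L 31, 35 and 38. Variation between vines was not measured, so these shares are not a rate of false differences between sites.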

Results

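The 6 libraries describe deseeded Cabernet Sauvignon berries from a low eastern site (Changli) and a high western site (Gaotai) at E-L 31, E-L 35 and E-L 38, with 1 library for each. In units of 1000 assigned reads, the Changli libraries held 8143, 8929 and 8555 at the successive stages, and the Gaotai libraries held 8301, 8493 and 8340. Of 47856 unigenes, 34091 had a read in all 6 libraries, 35769 matched a protein and 34815 of these matched a grape protein. The 10 most abundant unigenes took 4.01% of the Changli reads at E-L 31, 16.8% at E-L 35 and 19.2% at E-L 38, and 5.19%, 13.9% and 26.4% of the Gaotai reads. A unigene whose match in Medicago is labelled Cytochrome P450 likeTBP (CL3087.Contig2) alone had 440992 reads in Gaotai at E-L 38 and 40692 in Changli. Whether it is a coding transcript was not examined.

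The first comparison asks which transcripts changed at the onset of ripening, from E-L 31 to E-L 35, alike at both sites. Many transcripts of dividing and expanding green berries fell, among them most of the cell cycle and histone list, a tubulin, a light-harvesting protein and some tannin enzymes. The anthocyanin glucosyltransferase and its MYB regulator appeared, with a sugar exporter and chitinases. Transcripts typical of maturing seeds rose as well, although the berries had been deseeded. Of 28799 unigenes, 1947 rose and 3324 fell, and 5257 of these 5271 kept their sign in both regions. Leaving out Changli E-L 31 or Gaotai E-L 31 gave 2812 and 2294 unigenes, and scaling by library size alone moved the median of all unigenes to -0.44, so directions here are relative to the TMM scale.

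The last anthocyanin step and its regulator rose while most of the tannin genes named here fell. UFGT (Unigene2465), which adds glucose to anthocyanidins, had 3 reads at E-L 31 over both regions and rose by a count ratio of 576 (95% interval 197 to 2795). Its regulator MYBA1 (CL3780.Contig1) rose by 6.52 ± 0.45 (log2) and a glutathione S-transferase (Unigene924) by 7.49 ± 0.60. Both had 3 reads in Gaotai and 1 in Changli at E-L 31, so the size of these rises is uncertain. The tannin regulator MybPA2 (CL3505.Contig1) fell, at -6.90 ± 0.46, to 2 reads in Gaotai and 4 in Changli at E-L 35. Anthocyanidin reductase (ANR, Unigene1514) fell, at -5.96 ± 0.71, and a leucoanthocyanidin reductase (LAR, CL4779.Contig1) at -4.25 ± 0.92. LAR2 (CL5477.Contig1) moved far less, from 13.7 to 9.21 CPM in Changli and from 9.13 to 8.55 in Gaotai. The shared upstream genes fell too: F3H (CL3939.Contig1) at -4.04 ± 0.56, LDOX (Unigene871) at -2.97 ± 0.49, DFR (CL6694.Contig1) at -2.28 ± 0.52 and F3'5'H (CL628.Contig1) at -1.80 ± 0.37. The second F3H unigene, CL3939.Contig2, fell less, from 564 to 125 CPM in Changli and from 282 to 143 in Gaotai. At E-L 35 it had more reads than CL3939.Contig1 in both regions. Chalcone synthase unigenes fell where the test passed (CL196.Contig1 at -3.58 ± 0.31, Unigene1798 at -5.28 ± 0.39), while the most abundant one (Unigene823) did not pass (adjusted p = 0.116). These unigenes match nearly the same proteins, so which of them carried the change is uncertain. Adjusted p for the other genes named in this paragraph, apart from LAR2 and CL3939.Contig2, ran from 0.00039 for MYBA1 to 0.0248 for DFR.

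Growth and wall genes were among those with large falls. A polygalacturonase (Unigene6881) had a count ratio of 1854 (332 to 73250) between E-L 31 and E-L 35, and tubulin beta-1 (Unigene7727) was at least 122-fold lower at E-L 35. A proline-rich protein (Unigene716) fell, at -8.93 ± 0.41, and a nepenthesin-like proteinase (Unigene1907) fell, at -8.76 ± 0.71. Of the 107 unigenes of the cell cycle and histone list 66 fell and 3 rose over all genes tested, and 73 fell and 8 rose when adjusted over the list alone. Among them histone H2A (Unigene9712) fell, at -6.83 ± 0.70, and the mitotic kinase CDKB2-1 (Unigene6964) fell, at -6.41 ± 0.63. A chlorophyll a-b binding protein (Unigene4746) fell, at -5.81 ± 0.39, an aquaporin of the vacuole (Unigene5234) at -7.51 ± 0.66 and a phenylalanine ammonia-lyase (CL7085.Contig2) at -4.03 ± 0.36. The L-idonate dehydrogenase of tartrate synthesis (CL4657.Contig1) fell, at -3.42 ± 0.40.

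A sugar exporter and some defence genes rose. The exporter SWEET14-like (Unigene5927) had a count ratio of 982 (176 to 38820), an endochitinase (Unigene858) rose by 10.04 ± 0.65 and a class IV chitinase (CL3270.Contig1) by 7.60 ± 0.39. The pathogenesis-related list as a whole leaned the other way, with 12 of 77 higher and 22 lower over all genes, 17 and 27 adjusted over the list alone and a median of -0.67, and was not called (adjusted p = 0.278). Phosphoenolpyruvate carboxykinase (Unigene815) rose by 3.33 ± 0.28, a carotenoid cleavage dioxygenase (CL1812.Contig2) by 5.25 ± 0.64, and a xyloglucan endotransglucosylase (CL7029.Contig2) by 8.62 ± 0.37. Genes of late embryogenesis and oil use were also among those with large rises. A desiccation-related protein (Unigene4603) was at least 442-fold higher, a malate synthase (CL1890.Contig1) at least 260-fold higher and a late embryogenesis protein (Unigene8192) at least 181-fold higher. A peroxiredoxin (Unigene2636) had a count ratio of 3606 (647 to 142500), isocitrate lyase (CL4038.Contig1) of 1763 (488 to 14560) and an oleosin (Unigene2235) of 1813 (325 to 71660).

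Camera called 17 of the 30 lists with the preset correlation and none with the estimated one. The estimated version has 2 degrees of freedom, so the loss of calls does not show an effect of correlation. The sugar and lipoxygenase lists, with estimated correlations of -0.014 and 0, lost their calls as well. For photosynthesis the estimate was 0.492, far above the preset value, so neither version settles that list. The cell cycle list was lower (adjusted p = 9.74e-16; adjusted p = 0.27 with an estimated correlation). Seed storage was higher, with 11 of 13 members up, or 13 adjusted over the list alone (adjusted p = 1.94e-13; adjusted p = 0.27 with an estimated correlation); its median of 8.49 was 7.23 with members of few reads at their floor. Drought and late embryogenesis (LEA) genes were higher, 10 of 13 over all genes and 10 adjusted over the list alone, where 1 also fell (adjusted p = 1.39e-10; adjusted p = 0.27 with an estimated correlation). Phenylpropanoid entry was lower, with 6 of 17 down and 8 adjusted over the list alone (adjusted p = 0.000111; adjusted p = 0.497 with an estimated correlation). Terpene synthases were lower, 6 of 11 and 7 adjusted over the list alone (adjusted p = 0.000286; adjusted p = 0.497 with an estimated correlation), with a median of -3.39, or -3.54 at the floor. Photosynthesis was lower, 14 down and 1 up of 56, and 18 and 2 adjusted over the list alone (adjusted p = 0.000286; adjusted p = 0.634 with an estimated correlation). Lipoxygenases were lower, 8 of 18 and 14 adjusted over the list alone (adjusted p = 0.000452; adjusted p = 0.27 with an estimated correlation). Lignin genes were lower, 16 down and 4 up of 34 (adjusted p = 0.00258; adjusted p = 0.497 with an estimated correlation). Sugar genes were higher, 14 up and 3 down of 49 over all genes and adjusted over the list alone (adjusted p = 0.00258; adjusted p = 0.27 with an estimated correlation).

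Cell wall loosening had 34 down and 17 up of 86, and 42 and 21 adjusted over the list alone (adjusted p = 0.00571; adjusted p = 0.497 with an estimated correlation). Auxin genes had 32 down and 9 up of 119 (adjusted p = 0.00571; adjusted p = 0.27 with an estimated correlation). Gibberellin and brassinosteroid genes were lower (adjusted p = 0.0091; adjusted p = 0.353 with an estimated correlation), as were ethylene genes (adjusted p = 0.0107; adjusted p = 0.589 with an estimated correlation), MYB and WRKY factors (adjusted p = 0.0159; adjusted p = 0.597 with an estimated correlation) and cellulose synthases (adjusted p = 0.022; adjusted p = 0.353 with an estimated correlation). Glutathione and antioxidant genes were higher (adjusted p = 0.0152; adjusted p = 0.497 with an estimated correlation), and so were carotenoid genes (adjusted p = 0.0239; adjusted p = 0.597 with an estimated correlation). The medians of the sugar, glutathione and carotenoid lists, 0.39, 0.40 and 0.24 on the TMM scale, were below 0 with library size alone. The flavonoid core list was not called (adjusted p = 0.0852), with 11 down and 2 up of 46 over all genes and 12 and 2 adjusted over the list alone. Nor were the anthocyanin list (adjusted p = 0.133, 4 down and 2 up of 16, median -0.66), the proanthocyanidin list (adjusted p = 0.332, 2 of 5 down) and the flavonol list (adjusted p = 0.822, 4 down and 1 up of 32). The heat shock list had a median of -0.13, a mean of 0.21 and a test direction upward (adjusted p = 0.676).

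The second comparison asks what changed during ripening proper, from E-L 35 to E-L 38, alike at both sites. Fewer unigenes passed, and most fell. Some photosystem, aquaporin, late embryogenesis and wall-loosening transcripts declined, while stilbene synthases, a thaumatin-like protein and some other defence proteins rose. In the photosynthesis, aquaporin and wall-loosening lists most members did not pass, and no list was called with an estimated correlation. F3'5'H, which leads to delphinidin-type anthocyanins, rose again after its fall at véraison. There were 313 unigenes higher and 1151 lower at E-L 38, and 1460 of these 1464 kept their sign in both regions. Leaving out Gaotai E-L 38 gave 2446, and scaling by library size alone moved the median of all unigenes to -0.16.

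Among the genes that rose were F3'5'H (CL628.Contig1) by 2.04 ± 0.36 (adjusted p = 0.0265), a chalcone synthase (CL196.Contig1) by 1.81 ± 0.29 (adjusted p = 0.0185) and the glutathione S-transferase Unigene924 by 1.89 ± 0.40 (adjusted p = 0.0412). Stilbene synthase CL7054.Contig2 rose by 3.79 ± 0.77 (adjusted p = 0.0388) and CL7054.Contig1 by 3.57 ± 0.74 (adjusted p = 0.04); the members are close relatives, so which one rose is uncertain. UFGT (adjusted p = 0.442), MYBA1 (adjusted p = 0.178) and LDOX (adjusted p = 0.643) did not pass. The largest rises were in tryptophan aminotransferase (CL4425.Contig1) by 6.61 ± 0.33, an auxin-binding protein (CL4120.Contig1) by 6.56 ± 0.84, protease inhibitor 2 (Unigene6920) by 6.31 ± 0.66, pathogenesis-related protein 10.3 (CL5160.Contig1) by 5.76 ± 0.90 and glutelin type-A 2 (CL2430.Contig1) by 4.58 ± 0.42. A thaumatin-like protein (Unigene4027) rose by 3.66 ± 0.35, expansin-B2 (Unigene770) by 3.88 ± 0.38 and the exporter SWEET15 (Unigene1043) by 2.07 ± 0.28.

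The largest falls were in a nitrate transporter (CL3133.Contig1) at -7.55 ± 0.63, a galactose oxidase-like protein (Unigene2725) at -7.46 ± 0.41, a salicylate methyltransferase-like protein (Unigene8421) at -6.32 ± 0.43, a proline-rich wall protein (Unigene721) at -5.79 ± 0.34, a metallothionein-like protein (Unigene817) at -5.71 ± 0.44 and pectate lyase 5 (CL4211.Contig2) at -5.60 ± 0.37. NCED1 (CL33.Contig2) of abscisic acid synthesis fell, at -4.05 ± 0.53. The vacuolar invertase-like Unigene862 fell, at -3.20 ± 0.42, SWEET14-like (Unigene5927) at -2.70 ± 0.35 and isocitrate lyase (CL4038.Contig1) at -4.27 ± 0.31. LAR2 (CL5477.Contig1) fell, at -3.99 ± 0.44, the aquaporins PIP2 (Unigene1445) at -3.88 ± 0.42 and TIP1-1 (Unigene1053) at -3.55 ± 0.43, and the CBF4 factor (Unigene6917) at -5.35 ± 0.70. The endochitinase Unigene858 that rose at véraison fell, at -5.18 ± 0.52.

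Camera called 13 lists with the preset correlation and none with the estimated one, which again has 2 degrees of freedom. The aquaporin list, with an estimated correlation of -0.046, lost its call too. Photosynthesis was lower, 15 of 56 and 35 adjusted over the list alone (adjusted p = 2.82e-08; adjusted p = 0.562 with an estimated correlation). LEA genes were lower, 8 of 13 and 10 adjusted over the list alone (adjusted p = 1.21e-06; adjusted p = 0.454 with an estimated correlation). Ribosomal proteins were lower by a little, 175 of 215 below 0 with a median of -0.41 but 7 past the threshold and 1 adjusted over the list alone (adjusted p = 2.73e-06; adjusted p = 0.551 with an estimated correlation). Aquaporins were lower, 8 of 21 and 13 adjusted over the list alone (adjusted p = 4.88e-06; adjusted p = 0.454 with an estimated correlation). Stilbene synthases were higher, 4 of 7 and all 7 adjusted over the list alone (adjusted p = 6.26e-05; adjusted p = 0.551 with an estimated correlation), with a median of 3.44, or 3.39 at the floor. Wall loosening had 20 down and 3 up of 86, and 26 and 4 adjusted over the list alone (adjusted p = 0.000251; adjusted p = 0.551 with an estimated correlation), with a median of -0.98, or -0.56 at the floor. Ethylene genes had 14 down and 1 up, and 25 and 5 adjusted over the list alone (adjusted p = 0.000251; adjusted p = 0.551 with an estimated correlation). Cellulose synthases were lower as a list, although 5 of 45 fell and 4 rose over all genes, and 12 and 4 adjusted over the list alone (adjusted p = 0.00042; adjusted p = 0.454 with an estimated correlation). Lower too were proanthocyanidin genes (1 of 5 over all genes and 5 adjusted over the list alone, with a median of -3.99, or -2.66 at the floor; adjusted p = 0.00236; adjusted p = 0.454 with an estimated correlation), cold response (5 of 7, adjusted p = 0.00247; adjusted p = 0.454 with an estimated correlation), seed storage (adjusted p = 0.017; adjusted p = 0.551 with an estimated correlation) and lipoxygenases (adjusted p = 0.0201; adjusted p = 0.454 with an estimated correlation). Light and UV genes were higher with 17 of 20 above 0, none past the threshold over all genes, and 1 up and 1 down adjusted over the list alone (adjusted p = 0.0188; adjusted p = 0.454 with an estimated correlation). The flavonoid core list had a median of 0.02 and a mean of -0.59 and was not called (adjusted p = 0.501). Without its DFR-like members, a list chosen after its values were seen, the median was 0.76 with 14 of 18 above 0 and the list was higher (adjusted p = 0.0298; adjusted p = 0.498 with an estimated correlation). The pathogenesis-related list was not called (adjusted p = 0.118): 7 of 77 were higher and 7 lower, 9 and 14 adjusted over the list alone, with 56 below 0 and a median of -0.62.

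The third comparison is the one the study is about: which transcripts differed between the sites alike at all 3 stages. Few passed. The fit recovered 14.9% of simulated changes of 1 on the log2 scale and 91.0% of changes of 2, so smaller differences would mostly be missed. The simulation left out dispersion particular to single unigenes, so it does not show how many real differences of 2 or more would be found. CL1203.Contig3, at 4.02, did not pass (adjusted p = 0.365), nor did CL1235.Contig1, at -2.53 (adjusted p = 0.394). The unigenes that passed were nearly all read in Changli and all but missing in Gaotai, and none had a gene function attached. Known berry genes differed between the sites at single stages, and several of those differences changed in size or sign from stage to stage. Of 28799 unigenes 14 passed, 1 higher and 13 lower in Gaotai, and 1513 had an unadjusted p under 0.05; the DESeq2 Wald test called 85, of which 12 were among the 14. The counts on leaving out 1 library were 122, 37 and 154 without Changli E-L 31, 35 and 38, and 129, 39 and 190 without Gaotai E-L 31, 35 and 38. A filter of 5 CPM left 6, all lower in Gaotai. The balance of directions depended on the setting: DESeq2 had 47 higher and 38 lower in Gaotai, the fit with no filter 58 and 80, the fits without Changli or Gaotai E-L 31 59 and 63 and 64 and 65, and those without Changli or Gaotai E-L 38 46 and 108 and 58 and 132.

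The unigene with the most reads among these, CL3306.Contig1, was at -10.65 ± 0.62 (adjusted p = 0.00343), with 7739 reads in Changli E-L 35 and 1 in Gaotai E-L 35. CL726.Contig1 was at -10.23 ± 0.62 (adjusted p = 0.00353) and Unigene2135 at -9.06 ± 0.46 (adjusted p = 0.00251). In Gaotai at E-L 31, 35 and 38, CL726.Contig1 had 2, 2 and 0 reads and Unigene2135 had 2, 2 and 4. At least 256-fold lower in Gaotai was Unigene2848, with Unigene7077 at least 196-fold lower, Unigene6839 at least 154-fold lower and CL3177.Contig1 at least 108-fold lower. The other 6 had count ratios of Changli over Gaotai from 240 (42.7 to 9515) for CL6335.Contig3 to 1011 (280 to 8354) for Unigene2764. Unigene495, without a description, was higher in Gaotai by 4.0 ± 0.41 (adjusted p = 0.0419), and 13 of the 14 kept their sign at every stage. Unigene2848 had 0 reads in both regions at E-L 31, and CL6335.Contig3 had 1 in Changli and 0 in Gaotai. For these 2 the difference rests on the later stages.

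No gene with a described function passed. Higher in Gaotai at every stage were a tubulin beta chain (CL7198.Contig5) at 1.78 ± 0.26 and the wall enzyme XTH23-like (Unigene1245) at 1.84 ± 0.27, both with an adjusted p of 0.168. The glucosyltransferase UGT85A2 (CL817.Contig4) was at 1.76 ± 0.28 (adjusted p = 0.214) and the zinc finger factor ZAT11 (Unigene4177) at 1.89 ± 0.32 (adjusted p = 0.226). The cold factor DREB1E (Unigene6713) was at 1.67 ± 0.34, the ubiquitin ligase PUB23 (Unigene5772) at 1.91 ± 0.37 and glycogenin-1 (Unigene3169) at 2.54 ± 0.61. Lower in Gaotai at every stage were the exporter SWEET15 (Unigene952) at -1.31 ± 0.23 (adjusted p = 0.257), a lipid-transfer protein (Unigene2427) at -1.34 ± 0.23, the transporter ABCC4 (Unigene8766) at -1.04 ± 0.20, the light receptor adagio 3 (Unigene7089) at -1.27 ± 0.31, Lea14-A (Unigene2214) at -1.09 ± 0.27 and an extensin (CL5418.Contig1) at -1.85 ± 0.53.

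Camera called 4 lists between regions with the preset correlation, and for each adjusted p = 0.99 with an estimated correlation. The estimated version has 2 degrees of freedom here too, so it cannot decide whether correlation accounts for these calls. Heat shock was lower in Gaotai, 55 of 73 below 0 with a median of -0.33 (adjusted p = 4.56e-05; adjusted p = 0.99 with an estimated correlation), but no member passed over all genes or adjusted over the list alone. The cold response list was higher with a median of 0.93, none past over all genes and 3 adjusted over the list alone (adjusted p = 0.0421; adjusted p = 0.99 with an estimated correlation). The anthocyanin list was higher with a median of 0.51, none past over all genes and 1 adjusted over the list alone (adjusted p = 0.0421; adjusted p = 0.99 with an estimated correlation). Seed storage was higher with a median of 0.90 and no member past either way (adjusted p = 0.0421; adjusted p = 0.99 with an estimated correlation). These differences were not alike at all stages: at E-L 38 the median log2 ratio was -0.15 for cold response (3 above 0 and 4 below), 0.00 for the anthocyanin list, -0.01 for seed storage and 0.43 for heat shock. With no member past over all genes, 5 wall-loosening genes were higher and 2 sugar genes lower when adjusted over the list alone. The flavonoid core (adjusted p = 0.146), flavonol (adjusted p = 0.806) and ethylene (adjusted p = 0.956) lists were not called. For the sugar, lipoxygenase, abscisic acid, gibberellin and aquaporin lists the median and the mean lay on opposite sides of 0.

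At pea size (E-L 31) the flavonoid pathway, photosynthesis and heat shock genes had fewer transcripts in the Gaotai berries. The phenylpropanoid and stilbene genes were lower there as well, and the cell cycle, cold response and seed storage lists were higher. There were 1310 unigenes at least 2-fold higher and 1389 at least 2-fold lower in Gaotai, which is 8.81% of 30639. Each region is 1 library here, so none of this was tested against replicates.

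Chalcone synthase Unigene823 had a Gaotai over Changli ratio of 0.321 (95% interval 0.310 to 0.332), DFR (CL6694.Contig1) of 0.409 (0.393 to 0.426), LDOX (Unigene871) of 0.454 (0.444 to 0.465), F3H (CL3939.Contig1) of 0.456 (0.440 to 0.472) and ANR (Unigene1514) of 0.543 (0.524 to 0.562). F3'5'H (CL628.Contig1) was near parity at 0.884 (0.848 to 0.922). Among described unigenes with at least 200 reads in the higher library, the highest ratios were for snakin-1 (Unigene7591) at 13.4 (9.50 to 19.5), a U-box protein (Unigene11244) at 10.6 (7.0 to 16.6) and an ethylene synthesis gene, ACC synthase-like (Unigene5228), at 5.46 (4.93 to 6.06). The lowest among them were for small heat shock proteins, CL1946.Contig2 at 0.0374 (0.0159 to 0.0750) and Unigene3051 at 0.0531 (0.0286 to 0.0907), and a universal stress protein (Unigene2613) at 0.0789 (0.0635 to 0.0971). Some unigenes without a described function were lower still, such as CL3306.Contig1 with 6 reads in Gaotai and 2935 in Changli. The median log2 ratio was -1.03 for photosynthesis, -0.66 for heat shock, -0.52 for the flavonoid core, -0.80 for phenylpropanoid entry and -1.07 for terpene synthases, each below all 10000 matched random lists (percentile 0.0). The random lists ignore the correlation between members of a list, so the percentiles at this and the later stages are not tests. Stilbene synthases were at -1.57 (percentile 0.01), and the cell cycle list at 0.28 lay above all random lists (percentile 100). Cold response at 0.86 and seed storage at 0.66, a list of markers of the removed seeds, both lay at percentile 99.99. The seed storage median rests on few reads: legumin A had 15 in Gaotai and 9 in Changli. In the fit from E-L 31 to E-L 35, 6 of its 13 members had 0 to 3 reads at 1 of these stages.

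At véraison (E-L 35) the sites were furthest apart, with some seed storage transcripts far more abundant in Gaotai, stilbene transcripts less abundant and the pathogenesis-related list lower by a smaller amount. The last anthocyanin step was lower in Gaotai, while F3'5'H, ANR, HY5 and the anthocyanin regulator MYBA1 were higher. There were 2298 unigenes at least 2-fold higher and 2554 lower, or 15.84% of 30639. These are again single libraries without a test.

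The 2S albumin (Unigene800) had a ratio of 894 (550 to 1564), with 13779 reads in Gaotai and 16 in Changli, and legumin A (CL1036.Contig1) of 373 (296 to 475). A basic 7S globulin-like protein (Unigene1646) was at 18.8 (17.2 to 20.7) and a lipid-transfer protein (Unigene827) at 13.1 (12.2 to 14.1). A basic pathogenesis-related protein 1 (CL5899.Contig1) was at 0.00314 (0.00102 to 0.00734), and the extensins Unigene942 and Unigene795 were at 0.0327 (0.0199 to 0.0510) and 0.0328 (0.0178 to 0.0556). UFGT was at 0.394 (0.349 to 0.444), F3'5'H at 2.32 (2.12 to 2.54), ANR at 3.88 (2.71 to 5.68) and MYBA1 at 1.51 (1.19 to 1.91). FLS (Unigene5393), whose match is labelled flavonol synthase/flavanone 3-hydroxylase, was at 1.91 (1.56 to 2.35). The light factor HY5 (Unigene7842) was at 2.23 (1.68 to 3.0). Stilbene synthases had a median of -2.36 (percentile 0.01), heat shock of -0.66 and pathogenesis-related genes of -0.52 (percentile 0.0 for both), with 29 of the 77 pathogenesis-related genes at least 2-fold lower and 4 at least 2-fold higher. Seed storage at 1.39 and lignin at 0.72 lay at percentile 100, cold response at 1.41 at percentile 99.99, LEA genes at 0.65 at 99.9 and carotenoid genes at 0.61 at 99.96.

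At harvest (E-L 38) the flavonoid, photosynthesis and heat shock lists stood on the other side: their transcripts were more abundant in Gaotai. The anthocyanin genes UFGT, MYBA1 and F3'5'H were higher there, and the unigene taken as flavonol synthase (FLS, Unigene5393) was lower. There were 1963 unigenes at least 2-fold higher and 958 lower, or 9.53% of 30639. As at the other stages, each side is 1 library and nothing was tested.

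UFGT had a ratio of 2.57 (2.34 to 2.82), F3H (CL3939.Contig1) of 2.34 (2.10 to 2.62), chalcone synthase Unigene823 of 2.26 (2.16 to 2.36), MYBA1 of 2.22 (1.82 to 2.71), DFR of 2.12 (1.92 to 2.35), LDOX of 1.96 (1.84 to 2.10) and F3'5'H of 1.86 (1.78 to 1.95). The second F3H unigene, CL3939.Contig2, which had more reads, was at 0.900 (0.842 to 0.963), F3'H (Unigene1375) at 0.956 (0.881 to 1.04) and chalcone synthase Unigene1798 at 0.771 (0.374 to 1.54), so not every step was higher in Gaotai. FLS was at 0.294 (0.243 to 0.353), the RING-H2 protein RHA4a (CL1988.Contig2) at 0.184 (0.125 to 0.262) and a copper transporter (Unigene5712) at 0.237 (0.172 to 0.321). The flavonol list, mostly DFR-like, leaned the other way from FLS, with 21 of 32 above 0, 10 below and a median of 0.35 (percentile 99.3). Glycogenin-2 (CL2171.Contig5), with 287 reads in Gaotai and 0 in Changli, was at least 113-fold higher against a floor of 3 reads, with an exact lower limit of 91.4. A small heat shock protein (Unigene2939) was at 48.9 (27.7 to 95.3), glycogenin-1 (Unigene3169) at 21.9 (18.4 to 26.3) and a tropinone reductase (CL2868.Contig1) at 16.9 (13.7 to 20.9). Photosynthesis had a median of 0.79 and heat shock of 0.43 (percentile 100 for both), the flavonoid core of 0.42 (percentile 99.97), wall loosening of 0.24 (99.98), ribosomal proteins of 0.19 (99.99) and MYB and WRKY factors of 0.21 (99.81).

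**Figure D1:**
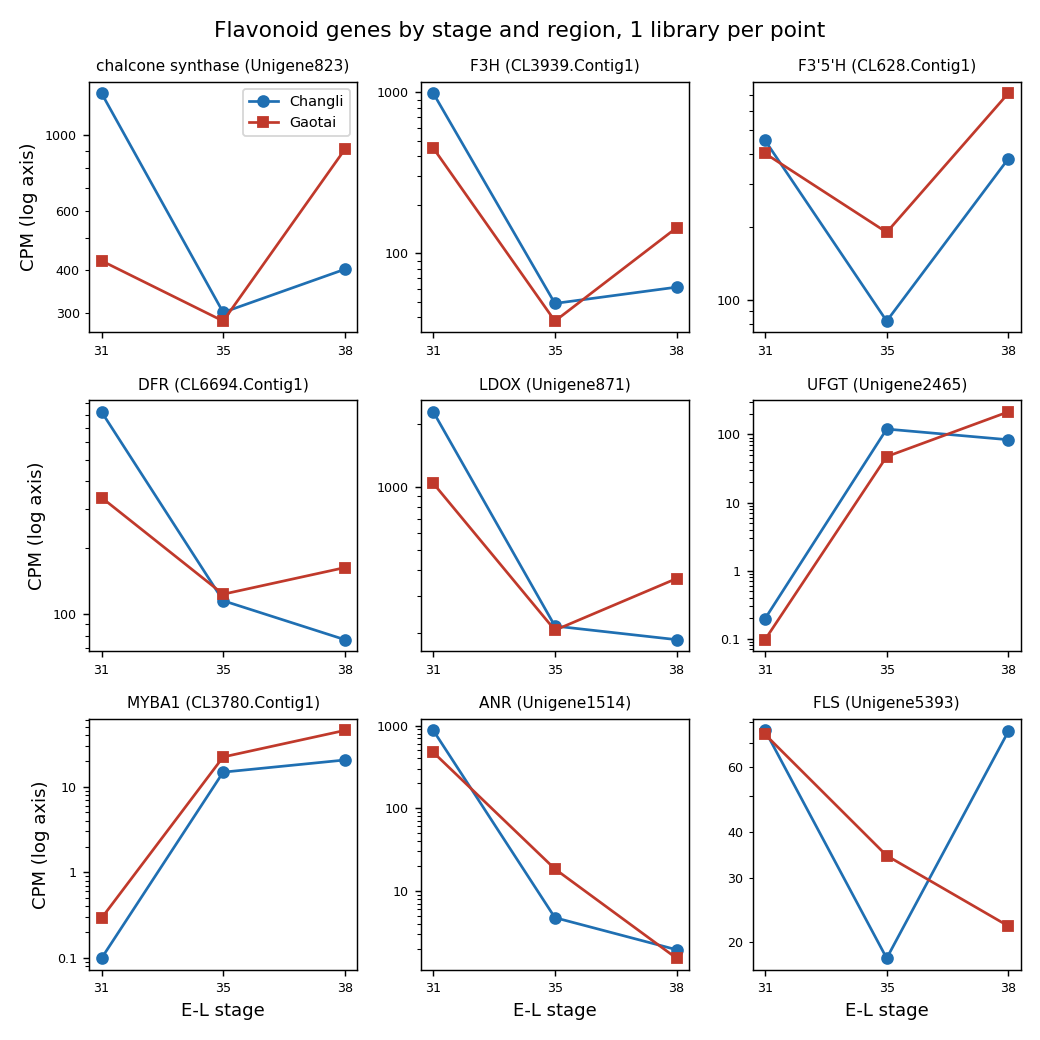
TMM-scaled CPM on a log axis against E-L stage for 9 flavonoid unigenes, Changli in blue circles and Gaotai in red squares, each point 1 library, so there are no error bars. Chalcone synthase Unigene823 stood at 1331 CPM in Changli and 427 in Gaotai at E-L 31, and at 403 and 909 at E-L 38.

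**Figure D2:**
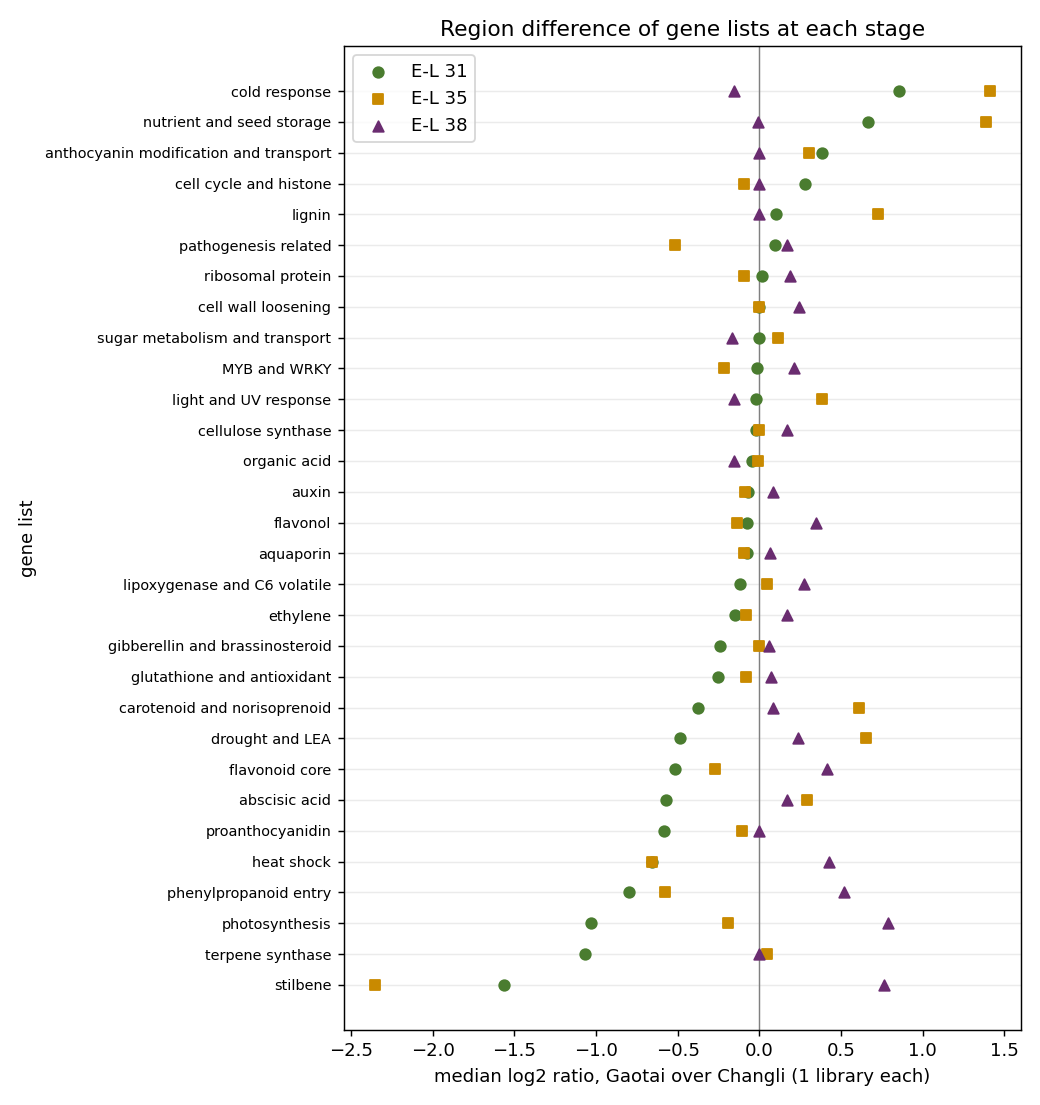
Median log2 ratio of Gaotai over Changli for the 30 gene lists, with circles for E-L 31, squares for E-L 35 and triangles for E-L 38, each from 1 library per region. Photosynthesis ran from -1.03 at E-L 31 to 0.79 at E-L 38.

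Across 28799 genes, the change from E-L 31 to E-L 35 in Changli and that in Gaotai were correlated at r = 0.794 (Spearman 0.699), and the change from E-L 35 to E-L 38 at r = 0.527 (Spearman 0.475). The region difference at E-L 31 and that at E-L 35 were correlated at r = 0.205 (Spearman 0.188). For E-L 35 and E-L 38 Pearson gave r = 0.089 and Spearman -0.019, and for E-L 31 and E-L 38 the values were r = -0.030 and -0.079. These 5 correlations are across genes, which are not independent replicates.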

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

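Of the tests in this part, those of another organism, of a single outside source, of seed RNA, of unigenes without a Changli read and of the ripening step next to a stage were chosen only after the result was seen, as were the percentile limits used to pick out lists. The other correlations with ripening, the share of unigenes read in 1 region alone and the splits of the libraries were planned. After the values were known, the planned limits were set aside for the ripening correlations at E-L 31 and E-L 38, and the share of unigenes was held to its whole interval; the verdicts that the planned limits would give are stated below. The check of the seed results without their extreme members was also added then.

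Several groups of genes stood on opposite sides at different stages, lower in Gaotai at one and higher at another, and were singled out for that reason. Each stage has 1 library per region, so the difference between stages was not tested for any of them. The median region difference of the flavonoid core list moved by 0.93 from E-L 31 to E-L 38 and by 0.69 from E-L 35 to E-L 38, on the log2 scale. Without its DFR-like members, a list chosen after its values were seen, the medians were -0.97 at E-L 31, -0.13 at E-L 35 and 0.55 at E-L 38, against -0.52, -0.27 and 0.42 with them, and at E-L 35 it was no longer extreme (percentile 15.87). Photosynthesis moved by 1.82 and 0.98 over the same intervals and heat shock by 1.09 and 1.08. From E-L 31 to E-L 35 the carotenoid and norisoprenoid list moved by 0.98 and the drought and LEA list by 1.14. Ribosomal proteins moved by 0.28 from E-L 35 to E-L 38. Among single genes the log2 ratio rose from E-L 31 to E-L 38 by 2.81 for chalcone synthase Unigene823, 2.63 for chalcone synthase Unigene859, 2.36 for F3H contig 1 and 2.37 for DFR, and from E-L 35 to E-L 38 by 2.70 for UFGT.

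One technical reading of these shifts is that berries of one site were further along in ripening when picked at the same E-L stage. The region difference would then follow the change with ripening across genes. The planned correlations used a change that shares no library with the stage: r was 0.012 (95% bootstrap interval -0.004 to 0.027) at E-L 31, 0.103 (0.086 to 0.117) at E-L 35 and 0.038 (0.024 to 0.052) at E-L 38. The bootstrap resampled genes with the libraries held fixed, so its intervals here and below cover no variation between libraries or vines. With added reads not scaled to library size, the first version computed, the 3 values of r were 0.014, 0.097 and -0.005. By the planned limit, an r under 0.1, the values at E-L 31 and E-L 38 would speak against a difference in ripeness. That limit was ill chosen, because at these stages the change is not the step next to the stage and the steps differ: the LEA list had a median of 6.40 from E-L 31 to E-L 35 and of -1.70 from E-L 35 to E-L 38. With the step next to the stage r was -0.069 (-0.083 to -0.055) at E-L 31 and -0.168 (-0.182 to -0.155) at E-L 38. These share both libraries of the stage, so unequal noise in the libraries would alone give a value other than 0, and neither their size nor their sign is read as a difference in ripeness. At E-L 31 the lists went both ways: of 9 that changed from E-L 31 to E-L 35 and lay at the extremes of the random lists, 5, photosynthesis among them (-1.07 with the step and -1.03 between regions), placed Gaotai further along, and 4, the cell cycle list among them (-2.29 and 0.28), placed it behind; for the carotenoid and glutathione lists among these, the step changed sign with library size only or RPKM + 1, which would place Gaotai further along. At E-L 38 all 3 such lists, photosynthesis (-1.97 and 0.79), wall loosening (-0.98, or -0.56 at the floor, and 0.24) and ribosomal proteins (-0.41 and 0.19), placed Gaotai behind. All these lists were called with the preset correlation alone, and none with an estimated one, where the test has 2 degrees of freedom. A difference in ripeness could therefore contribute at each stage and cannot be told apart from a difference between sites, since each stage has 1 library per region. Altitude and whatever else sets the sites apart go with region and stay open, untested.

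The 13 unigenes lower in Gaotai had 36460 reads in Changli and 28 in Gaotai. RNA of another organism in the Changli berries is a candidate explanation: 12 of the 13, or 92.3%, had no protein match, against a median of 15.4% and an upper 95% limit of 38.5% in random lists matched on length, though noncoding grape RNA would lack a match too. A single outside source of fixed composition is argued against, since the unigenes moved apart between stages in Changli, with an SD of 1.97 (log2) from E-L 31 to E-L 35, where some had 0 or 1 reads, and of 1.19 from E-L 35 to E-L 38, where all had at least 56. Unigenes assembled from Changli reads alone stay open. There were 532 unigenes without a uniquely assigned Changli read, and 6 of these had at least 20 reads in Gaotai. The counts leave out reads that were not unique, and the reads used for the assembly are not given, so these 6 do not decide it. The deposited unigene names end in CLI-a, a suffix whose meaning is not given and which was dropped here. The planned share points towards such an assembly: of 62 unigenes with at least 20 reads in 1 region and none in the other 9.7% were read in Gaotai alone, under the planned limit of 10% that would speak for it, although the interval (3.6% to 19.9%) spans that limit. An assembly that drew mostly on Changli reads was not tested. Of the 10 splits of the 6 libraries into 3 and 3, 3, the real one included, gave at least as many unigenes as the real 14, and the highest of the others gave 21; 10 splits are too few for a share under 0.05. With stage in the fit, both splits with 21 divide the E-L 35 pair alone, so they rest on the difference between the E-L 35 libraries. They are the same fit with the sign turned, so the 10 splits count this alternative more than once. Among the 4 splits with 1 library of each stage per side the highest other gave 1.

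Seed storage and LEA transcripts rose at E-L 35 in deseeded berries, and the 2S albumin and legumin were abundant in Gaotai at that stage alone. Seed RNA in the sample is a candidate source, because these lists name transcripts of seeds. One seed RNA diluted from E-L 35 to E-L 38 was judged by the SD of the change across the 21 members. It was 2.63 in Gaotai, above the median of 1.07 in random lists, and 1.40 in Changli, above 1.27. By the limit written first, an SD above that median, this speaks against one dilution of all 21. Without glutelin A2 and legumin the SD was 1.02 in Gaotai and 0.74 in Changli over the other 19. The random lists kept their own extreme members, so these lower values do not decide the question for the 19. More of the same seed RNA in Gaotai at E-L 35 was judged by the SD of the ratio, under 1 for it and above 2 against it. The SD was 2.71 across 11 seed list members whose log2 ratios ran from -1.88 to 8.53. By these limits it speaks against a uniform increase of all 11. It was 1.51 over 10 without legumin and 1.22 over 9 without glutelin A2 as well, between the limits, so for those members the explanation stays open. The 2S albumin, with a log2 ratio of 9.80, is not among the 11, because its rise from E-L 31 to E-L 35 did not pass; a uniform increase of one seed RNA would not by itself give the far higher ratios of legumin and the albumin. Seed tissue of differing maturity at the sites, and expression in the berry itself, stay open and were not tested.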

How the results depend on the processing

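The alternatives that summed unigenes with one protein match, left out the 3 most abundant Medicago-matching unigenes, dropped the DFR-like members from the flavonoid core list, or used added reads not scaled to library size were chosen only after the result was seen.

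The 14 unigenes differing between regions became 23 with library size only, 138 with no filter, 6 with a filter of 5 CPM, 85 with the DESeq2 Wald test, 2 with limma on RPKM + 0.1, 7 with unigenes summed by protein match, and 0 without the stage block, where the stage changes enter the error; leaving out 1 library gave 37 to 190. The lists called between regions went from 4 to 1 with limma on RPKM + 1 and to 6 with library size only. The cause was not tested.

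The 5271 unigenes from E-L 31 to E-L 35 ranged from 2294 to 7360 on leaving out 1 library. The 1464 from E-L 35 to E-L 38 became 2929 at an adjusted p of 0.1, 2939 with no filter, 2248 with DESeq2 and 833 with limma on RPKM + 0.1, and 1056 to 2446 on leaving out 1 library. With 1 library left in a group, that library is assumed to vary like the others. Unigenes at least 2-fold apart fell, with a filter of 5 CPM, to 1059, 2229 and 1486 at E-L 31, 35 and 38, since fewer were considered, and at 4-fold to 589, 1834 and 857. RLE scaling kept all 14 regional unigenes, 5114 of the 5271 and 1435 of the 1464.

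The correlation of region differences at E-L 35 and E-L 38 changed sign with Spearman, to -0.019, and was 0.175 with a filter of 5 CPM. With Spearman and with that filter, the others were 0.188 and 0.225 (E-L 31 and 35), -0.079 and -0.018 (E-L 31 and 38), 0.699 and 0.85 (change from E-L 31 to 35), and 0.475 and 0.625 (change from E-L 35 to 38, 0.513 with RPKM). The cause was not tested.

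From E-L 31 to E-L 35, library size only and limma on RPKM + 1 reversed the medians of the carotenoid list (-0.167 and -0.131), the glutathione list (-0.018 and -0.011) and the sugar list (-0.017 and -0.038); both settings move the median of all unigenes, to -0.44 and -0.30. Without its DFR-like members the flavonoid core list was lower at E-L 35 (adjusted p = 4.83e-05; adjusted p = 0.271 with an estimated correlation). No gene named above reversed a call: over their alternatives 5797 values kept direction and side of the threshold, 282 passed it and 202 no longer did. A further 185 values of genes that were not called changed sign, 145 of them on leaving out 1 library. Depth limits the single-library ratios, where 1.13% to 1.37% of simulated unigenes without a difference were counted. Variation between vines, which was not measured, would come on top of this.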

Other observations

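All values in this part were chosen only after the result was seen, and they carry no test. Beyond the unigenes past the threshold, 43 unigenes had at least 100 reads in Changli and under 1% of that in Gaotai, and 34 of these had no protein match. Unigene2380, which matched a protein of the alga Volvox, had 19879 reads in Changli at E-L 35 and at most 6 in each other library. Unigene8002, which matched a barley protein, had 4920 reads in the same library and at most 2 elsewhere. In the reverse direction there were 3 unigenes: legumin A, the 2S albumin and Unigene2129, a grape protein without a described function that had 1438 reads in Gaotai at E-L 35 and at most 1 in each other library. Counting every unigene, 532 had no read in Changli and 586 had none in Gaotai.

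The Medicago-matching unigenes took a changing part of each library. CL3087.Contig2 had 14124, 100056 and 40692 reads in Changli at E-L 31, 35 and 38, and 35077, 25978 and 440992 in Gaotai.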
